A study of Caenorhabditis elegans with 2 samples.

How the data were processed

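Anti-GFP ChIP-seq was carried out on whole L4 hermaphrodites of a strain that expresses GFP-tagged ROW-1, in 2 biological replicates of 1 group, and chromatin was fragmented by sonication, per the labels. For each of the assemblies ce10 and ce11 there were 4 lists in narrowPeak format: a call list of each replicate that holds peaks and background as input for an irreproducible discovery rate (IDR) analysis, a pooled list of the same kind, and an optimal list of peaks past the IDR threshold, per the deposited file listing. Each call list was derived from alignments and 1 further file that is not used here. The aligner, the peak caller, their versions, the IDR threshold and the scale of the signal are not given in the sources used here. The strength of each peak is a signal value as the authors deposited it, used here only to rank, filter and describe peaks within a list. The lists also hold the −log10 of a q-value from the authors' caller, which was tied at its maximum of 3.02 in all 1574 optimal peaks and so did not rank them. No read counts were used, so the depth per sample is unknown, and signals of different lists are not on a known common scale: over the peaks with a call in both, the median ratio of replicate 1 to replicate 2 was 1.42.

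Peak positions on ce11 were set against Ensembl release 115 gene models and the RefSeq sequence of the same assembly (WBcel235). No coordinate was converted between assemblies (matches within 1 kb used positions as deposited), and no gene was assigned on ce10. The last pooled call on X ended at 17718942, the length of X in the reference. A promoter ran from 500 bp upstream to 200 bp downstream of an annotated 5' end. Each summit was given 1 class, in the order promoter, 5' UTR, coding exon, intron, 3' UTR, noncoding or pseudogene exon, intergenic; the exons of noncoding genes and pseudogenes were set apart from intergenic sequence after the data were seen. Overlaps and class shares were compared with 1000 circular shifts of all positions within each chromosome, which keep the spacing of peaks. Shifts of the replicate lists and of promoter shares were tested one-sided, and the classes two-sided with Benjamini-Hochberg adjustment. The shares on X and in the middle 50% of each autosome were tested two-sided on nuclear peaks against 100000 random draws by length. Intervals of shares are exact Clopper-Pearson intervals at 95%.

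A protein-coding gene had a promoter peak where a summit lay in any of its promoter windows. Genes were grouped in 35 lists by gene name or by typed symbols, and each list was tested against all other nuclear protein-coding genes by a two-sided Fisher's exact test, adjusted over the lists, with a threshold of 0.05. For sequence, the presence of each 6-mer, with both strands merged, among the positions within 50 bp of the summit was compared with flanks of the same total length 250 to 300 bp away by an exact McNemar test, adjusted over 2080 6-mers. For the replicate signals, the strongest call of each replicate that overlapped an optimal peak by 1 bp was taken.

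The genes named follow a rule: row-1 and unc-119 in any case, the genes or positions of the 20 optimal peaks with the highest signal, up to 4 members with the strongest peaks of each enriched list, up to 2 of each depleted list, and 1 of each of the 6 lists closest to the threshold among the others. The tests, lists, alternatives and this rule were fixed before the data were examined. Alternatives were other promoter windows, peak overlap in place of the summit, the 787 strongest peaks, the 3148 strongest pooled calls, the strongest calls of 1 replicate alone (without replicate 1 or without replicate 2), protein-coding genes only, other backgrounds, circular shifts for the gene lists, and 8-mers or other distances for the sequences. The shares of noncoding gene types, the results on nuclear peaks only, the separate sequence tests of X and autosomes, the circular shifts for distances, for promoter shares of X and autosomes and for matches between assemblies, the signals at equal numbers of calls per Mb (with 1000 bootstrap draws of 1-Mb blocks), and the motif tests were added after the data were seen.

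The tests were tried on simulated data. With random genes among 19973, no list was called in any of 20 rounds (0 of 20), and a list with planted genes was called in 20 of 20. Uniform summits (1500 per round) gave 0 calls of the promoter share in 20 rounds and planted ones 20. Over 5 rounds of uniform summits, 1 6-mer was called in all, and a planted 6-mer ranked first in 5 of 5. Unrelated lists were called as overlapping in 0 of 20 rounds and lists with shared peaks in 20 of 20. Uniform summits were placed without regard to GC content, which differs between the real summits and their flanks. Random genes were drawn without regard to position, although neighbouring genes can share a real peak. The simulated rounds therefore give no rate of false calls from either of these features. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.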

Results

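The DNA bound by ROW-1 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the nematode Caenorhabditis elegans. The row-1 gene (F37D6.2) encodes a protein with C2H2 zinc fingers, a domain type that often contacts DNA. A transgenic strain, OP510, carried row-1 with a C-terminal GFP-FLAG tag, and an antibody against GFP recovered the tagged protein with its bound DNA. Whole hermaphrodites were collected at the L4 stage, the last larval stage, 48 h after starved L1 larvae had been synchronized. The series held 1 group of 2 biological replicates, so the questions are where the tagged protein was found along the genome and how alike the replicates were. No contrast of conditions exists. The deposited values were peak lists, so the read depth is unknown, and intervals given for shares cover counting error only. No control library and no other tagged strain was examined here. Signal that sites may yield with any GFP-tagged protein is therefore not separated from binding by ROW-1 in any result below. Positions are on ce11 and counted from 1 unless ce10 is named.

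Both replicates placed most of their strongest calls at shared sites. Of the 1574 strongest calls of replicate 1, 1207 (76.7%) overlapped one of the 1574 strongest calls of replicate 2 by at least 1 bp, against 2.55% on average when the calls were shifted around the chromosomes (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction the overlap was 1204 of 1574 (76.5%). The final list that the submitters made from both replicates, called the optimal list below, held 1574 peaks in 1506 separate regions that covered 571 kb, or 0.570% of the genome. Its peak signals, which are the authors' own values, ran from 74.8 to 4375 with a median of 115. Of the 1574 peaks, 1428 (90.7%) were among the 1574 strongest calls of replicate 1, 1332 (84.6%) among those of replicate 2, and 1196 (76.0%) among both, although the list was made from these replicates and is no independent measure of them. Over the 1571 peaks with a call in both, the log2 signals had a Spearman's rho of 0.745 (bootstrap 95% interval 0.713 to 0.771) and a Pearson's r of 0.883. These correlations run across peaks, which are not independent replicates, and carry no p-value.

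The row-1 locus itself carried no call. Neither the optimal list nor the longer pooled and replicate lists had a call within 1 kb of row-1 (WBGene00009508, chromosome I, 10475519 to 10478129, minus strand). At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the gene of the mutation that the strain's genotype names, the optimal list also had no peak. The pooled list had 7 calls within 1 kb of unc-119. The strongest, at 10903227 to 10903656 with its summit in an intron, had a signal of 68.1 and rank 1801 of 30000, below the lowest optimal signal. Its counterparts had a signal of 43.8 in replicate 1 and 29.8 in replicate 2.

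ROW-1 peaks lay mainly at promoters when genes of every type were counted. Of the 1574 summits, 1081 (68.7%, exact 95% interval 66.3 to 71.0) fell between 500 bp upstream and 200 bp downstream of an annotated 5' end of a gene of any type, 2.70 times the 25.4% found after circular shifts (one-sided permutation p = 0.001, the smallest possible). With promoters of protein-coding genes only, the count was 741 (47.1%), against 16.5% after shifts (one-sided permutation p = 0.001). The 1574 strongest calls of each replicate alone, with genes of any type, gave 67.2% ± 0.99 (SD, n = 2). The bodies of genes held few summits. Coding exons had 18 summits (1.14%) against 19.6% after shifts, introns 145 (9.21%) against 27.4%, and 3' UTRs 2 (0.127%) against 2.52%, each with an adjusted two-sided permutation p = 0.0028. These small shares moved between alternatives while staying below their shifts: coding exons had 2.16% without replicate 1, 0.699% without replicate 2 and 0.254% with promoters from 1000 bp upstream to 500 bp downstream. In the same order 3' UTRs had 0.826%, 0.318% and 0.0635%, and 0.826% by peak overlap, and introns had 17.1% with promoters of protein-coding genes only. Exons of noncoding genes and pseudogenes had 6 summits (0.381%) against 1.42% (adjusted permutation p = 0.0028), and 5' UTRs outside promoter windows had 12 (0.762%) against 0.468%, which did not pass (adjusted permutation p = 0.176). Intergenic sequence outside promoter windows had 310 summits (19.7%) against 23.2% (adjusted permutation p = 0.0117). This last difference changed direction with a narrower window or with promoters of protein-coding genes only, where intergenic shares were 30.8% and 33.2%.

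**Figure D1:**
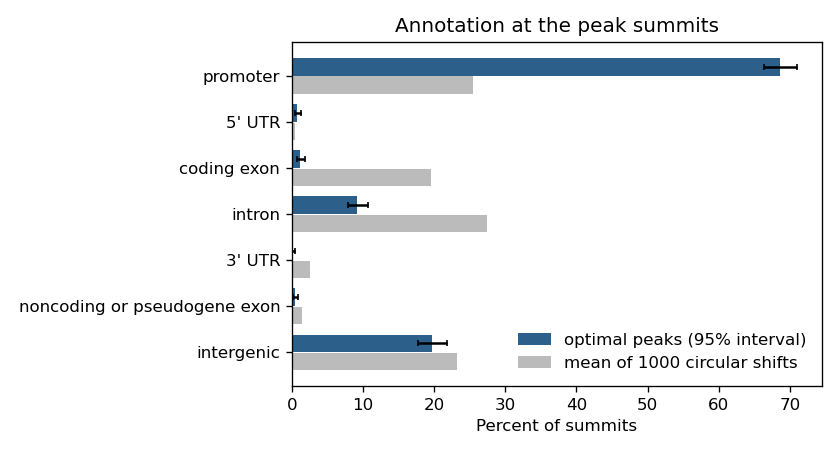
Percent of the 1574 peak summits in each annotation class (blue bars, with exact 95% intervals) beside the mean of 1000 circular shifts of the same summits (grey bars). Promoters of genes of any type hold 68.7% of the summits against 25.4% after shifts, and coding exons hold 1.14% against 19.6%.

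Summits sat closer to the 5' ends of protein-coding genes than shifted positions did, and mostly upstream. Over the 1553 nuclear peaks, the median distance to the nearest such end was 512 bp (quartiles 191 and 1659 bp) against 1349 bp on average after circular shifts, and 26.7% of the summits lay within 200 bp of it against 9.77%. Upstream of that end lay 75.5% of the summits, against 43.8% after shifts (two-sided permutation p = 0.0020 for each of these 3 values). A protein-coding promoter was occupied by 729 peaks, of which 207 (28.4%) lay in the promoter windows of 2 or more genes, so some neighbouring genes share a peak. In all, 914 of the 19973 nuclear protein-coding genes (4.58%) had a promoter peak.

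In the main promoter window, genes of cytosolic ribosomal proteins stood out among the promoters with a peak. Cytosolic ribosomal protein genes had a promoter peak in 44 of 81 cases (54.3%, exact 95% interval 42.9 to 65.4), against 4.37% of other protein-coding genes (odds ratio 26, adjusted exact p = 4.66e-36). In the narrower window from 250 bp upstream to 100 bp downstream the count was 9 of 81 (11.1%, odds ratio 4.34, adjusted exact p = 0.00274). Odds ratios there were higher for translation factors (9.26), RNA polymerase and Mediator (8.68) and the respiratory chain (7.42), among others. By the nearest gene of each summit the ribosomal count was 28 (34.6%, odds ratio 7.41, adjusted exact p = 3.23e-12). Synaptic and neuronal (13.9) and heterochronic genes (12.5) had higher odds ratios by that assignment. With the 787 strongest peaks the ribosomal count was 26 (32.1%, adjusted exact p = 1.70e-21). The strongest were rpl-3, with a signal of 1231 (682 in replicate 1 and 551 in replicate 2) and its summit 271 bp upstream of the 5' end, at position 3867583 of chromosome III, and rpl-20, with a signal of 796 at position 4750066 of chromosome IV. rpl-35 and rpl-15 followed with 601 and 598. Translation factors had a peak in 11 of 38 genes (28.9%, adjusted exact p = 3.91e-06). Among them were iff-2 (signal 374), the initiation factor gene eif-3.C (309) and the elongation factor genes eef-1A.2 (268) and eef-2 (237). Mitochondrial ribosomal protein genes had a peak in 9 of 70 cases (12.9%, adjusted exact p = 0.0105), led by mrpl-28 with a signal of 165, mrpl-55 with 123, mrps-7 with 122 and mrpl-45 with 105. In the narrower window their share was 11.4% (adjusted exact p = 0.00349). This list was no longer called by nearest gene (14.3%, adjusted exact p = 0.0575) or with the 787 strongest peaks (4.29%, adjusted exact p = 0.426). Aminoacyl-tRNA synthetase genes did not pass, with 2 of 32 (6.25%, adjusted exact p = 0.793). These and the following adjusted exact p-values of gene lists are from two-sided Fisher's tests with Benjamini-Hochberg adjustment over 35 lists.

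Genes of energy supply, nuclear transport and protein folding also had promoter peaks more often than other genes. The respiratory chain and ATP synthase list had 12 of 34 genes with a peak (35.3%, adjusted exact p = 1.98e-07), led by the cytochrome c oxidase genes cox-5A (signal 513) and cox-5B (345), with atp-1 at 299 and cox-6B at 219. Nuclear pore and transport genes had 12 of 37 (32.4%, adjusted exact p = 4.41e-07), with the nucleoporin genes npp-3 (316), npp-14 (171) and npp-8 (128) and the importin gene imb-3 (133). Chaperone genes of the heat shock list had 13 of 49 (26.5%, adjusted exact p = 1.41e-06), including hsp-90 (469), hsp-1 (383), hsp-3 (301) and dnj-19 (283). The hsp-90 and cox-6B summits lay inside their gene models, 382 and 145 bp upstream of an internal annotated 5' end. The dnj-19 summit lay 382 bp from its 5' end and 14 bp from that of nhr-47. The proteasome list had 5 of 33 (15.2%, adjusted exact p = 0.0355), led by rpn-3 (242) and rpn-11 (121), then pas-4 (98.4) and rpn-2 (80.5). The autophagy and lysosome list had 8 of 48 (16.7%, adjusted exact p = 0.00403), with epg-7 (239), lgg-2 (189), hlh-30 (148), which encodes the TFEB orthologue that regulates autophagy genes, and vha-12 (134). In the narrower window the shares fell to 17.6% for the respiratory chain, 10.8% for nuclear pore and 14.3% for heat shock genes, all still past the threshold, and to 8.33% for autophagy and lysosome genes, which were no longer called (adjusted exact p = 0.0858). By nearest gene the nuclear pore share was 18.9% and the heat shock share 16.3%, both past the threshold, and the proteasome list was not called (18.2%, adjusted exact p = 0.0508), nor was it with the 787 strongest peaks (6.06%, adjusted exact p = 0.363).

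Genes of RNA synthesis and processing and of chromatin formed a further set. Spliceosome genes had 9 of 33 with a peak (27.3%, adjusted exact p = 5.29e-05), including the Sm protein genes snr-4 (216) and snr-1 (150) and the neighbours rsp-1 and rsp-2, which share 1 peak with a signal of 179. RNA polymerase and Mediator genes had 8 of 40 (20%, adjusted exact p = 0.00145), with rpb-11 at 202, mdt-26 at 152, mdt-9 at 104.1 and mdt-22 at 100.5. Histone modification genes had 9 of 68 (13.2%, adjusted exact p = 0.00924), led by set-16 (436), set-21 (314), set-4 (265) and met-1 (200.2). The DNA replication and cell cycle list had 8 of 54 (14.8%, adjusted exact p = 0.00806). Its strongest member, cdc-48.1 with a signal of 739, encodes a segregase ATPase of protein turnover, and cdc-6 (163), cdk-5 (119.03) and cdk-7 (115) followed. The vulval induction list had 7 of 34 (20.6%, adjusted exact p = 0.00238). Its 4 strongest members, lin-54 (427), lin-53 (293), lin-9 (234) and lin-35 (197), encode the Rb homologue and partners of the DRM repressor complex rather than the growth factor signalling proteins that the list also holds. In the narrower window the shares were 15.2% for spliceosome, 11.8% for vulval induction and 8.82% for histone modification genes, all still past the threshold. By nearest gene and with the 787 strongest peaks, RNA polymerase and Mediator genes (15% and 5%, adjusted exact p = 0.0986 and 0.434) and DNA replication and cell cycle genes (14.8% and 7.41%, adjusted exact p = 0.0575 and 0.0964) were no longer called. Among genes that had any call of the pooled list at the promoter, 5 enriched lists besides mitochondrial ribosomal proteins were no longer called: proteasome, RNA polymerase and Mediator, DNA replication and cell cycle, histone modification, and autophagy and lysosome. With 1 replicate alone, the 13 enriched lists became 11 without replicate 1 and 15 without replicate 2. Without replicate 1, the proteasome list (9.09%, adjusted exact p = 0.226) and the RNA polymerase and Mediator list (12.5%, adjusted exact p = 0.0599) were not called. Without replicate 2 their shares were 21.2% and 20%.

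**Figure D2:**
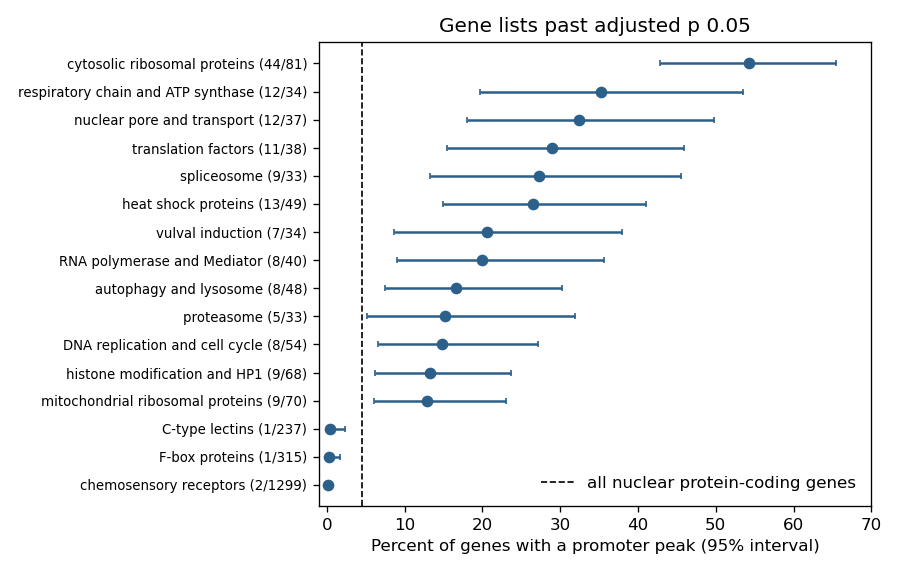
Percent of the genes of each list with a promoter peak (points, with exact 95% intervals; counts in parentheses) for the 16 lists past the threshold, with the share of all nuclear protein-coding genes (4.58%) as a dashed line. Cytosolic ribosomal protein genes reach 54.3%, and chemosensory receptor genes lie at 0.154%.

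Genes of chemosensory receptors, F-box proteins and C-type lectins were almost free of peaks. Chemosensory receptor genes had 2 with a peak among 1299 (0.154%, adjusted exact p = 3.43e-23), sri-5 (signal 177) and srh-16 (156), and the list stayed depleted against circular shifts of the peaks (adjusted permutation p = 0.0219). F-box genes had 1 of 315 (0.317%, adjusted exact p = 4.49e-05), fbxb-85 with a signal of 314, and C-type lectin genes had 1 of 237 (0.422%, adjusted exact p = 0.00145), clec-126 with 137. Neither of these last lists was depleted against circular shifts, with an adjusted permutation p of 0.528 for F-box genes and 1 for lectins. Their shifted means were 1.06% and 0.912%, which leaves little room for a depletion to show in lists of this size. With the 787 strongest peaks lectin genes were not called (adjusted exact p = 0.111).

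The other 19 lists did not pass with the main settings. Histone genes had 6 of 50 with a peak (12%, adjusted exact p = 0.0522), with his-37 at a signal of 561, and nuclear hormone receptor genes had 5 of 269 (1.86%, adjusted exact p = 0.0522), with nhr-47 at 283 from a peak it shares with dnj-19. Synaptic and neuronal genes had 4 of 30 (adjusted exact p = 0.0851), with rgef-1 at 167, and heterochronic genes 2 of 19 (adjusted exact p = 0.314). Both depended on how peaks were assigned: by nearest gene 15 of 30 synaptic and neuronal genes (50%, odds ratio 13.9, adjusted exact p = 1.83e-09) and 9 of 19 heterochronic genes (47.4%, adjusted exact p = 1.01e-05) were called. In the window from 1000 bp upstream to 500 bp downstream the counts were 7 of 30 (23.3%, adjusted exact p = 0.00416) and 6 of 19 (31.6%, adjusted exact p = 0.00183). Of the 9 alternatives, the synaptic and neuronal list was called in 5, histones and nuclear hormone receptors in 4 each, the heterochronic list in 3, and collagens and cytochrome P450 in 2 each. Collagen genes had 2 of 156 (adjusted exact p = 0.0851), with col-71 at 142. Cytochrome P450 genes had 0 of 74 and UDP-glucuronosyltransferase genes 0 of 67, which allow shares of up to 4.86% and 5.36% (exact 95% upper limits). Tissue lists gave 1 of 30 muscle genes, 1 of 38 cilia genes, 1 of 40 germline genes, and 0 of 29 genes in each of the intestine list and the epidermis and molting list. Major sperm protein genes had 0 of 31 and T-box genes 0 of 20. Homeobox genes had 3 of 82, bHLH genes 3 of 33, spermatogenesis genes 2 of 24 and Wnt signalling genes 1 of 29.

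The X chromosome held more peaks than its length predicts, and the strongest nuclear peaks lay on it. X had 351 of the 1553 nuclear peaks (22.6%, exact 95% interval 20.5 to 24.8), against 17.7% of the nuclear sequence and 13.7% of nuclear protein-coding genes (two-sided p = 1e-05 against each by 100000 random draws, the smallest they can give). Its density was 19.8 peaks per Mb, beside 19.7 on III, 18.6 on I, 14.7 on II, 13.1 on IV and 9.46 on V. Random draws treat peaks as independent, so their p-values do not measure the spread between chromosomes, and the density of X was near that of III. Among the 20 strongest nuclear peaks 16 lay on X, and among the weakest 753 the share on X was 20.6%. Each replicate alone also had 16 of its 20 strongest nuclear calls on X. On the autosomes, 724 of 1202 summits (60.2%, exact 95% interval 57.4 to 63.0) lay in the middle 50% of their chromosome (two-sided p = 1e-05 by random draws), and the excess was smaller against the 55.7% of protein-coding 5' ends found there (p = 0.00146 by random draws).

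The 20 strongest peaks of the optimal list were split evenly, 10 on the mitochondrial chromosome and 10 on X. The mitochondrial ones had signals from 1450 to 4375, the highest at 4187 to 5548 with its summit in a coding exon. The strongest on X, at 11093787 to 11094566, had a signal of 1720 (944 in replicate 1 and 780 in replicate 2) and an intergenic summit 3979 bp from the nearest protein-coding 5' end, that of W02H3.3. The next, at 9465473 to 9466236 (intergenic) and 6296134 to 6296965 (intronic), had 1649 and 1620. Intergenic peaks at 14525359 to 14526473, 4208532 to 4209682, 13700492 to 13701215, 11937171 to 11937889 and 16056177 to 16056929 had signals of 1526, 1482, 1383, 1319 and 1273, and an intronic peak at 2996587 to 2997514 had 1369. The only one of the 10 in a promoter window, at 8035973 to 8036981 with a signal of 1472, lay 250 bp upstream of the noncoding gene C18A11.13, and its nearest protein-coding gene was xol-1, the switch gene of sex determination, 4889 bp away. Because 10 of these 20 lay on the mitochondrial chromosome, further nuclear peaks were named after their values were seen. These are the autosomal peaks at rpl-3, at tasp-1 (signal 882, position 10759250 of III) and at Y17G9B.5 (796, the peak it shares with rpl-20), and one in a noncoding exon at 1151266 to 1151749 of V (946).

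**Figure D3:**
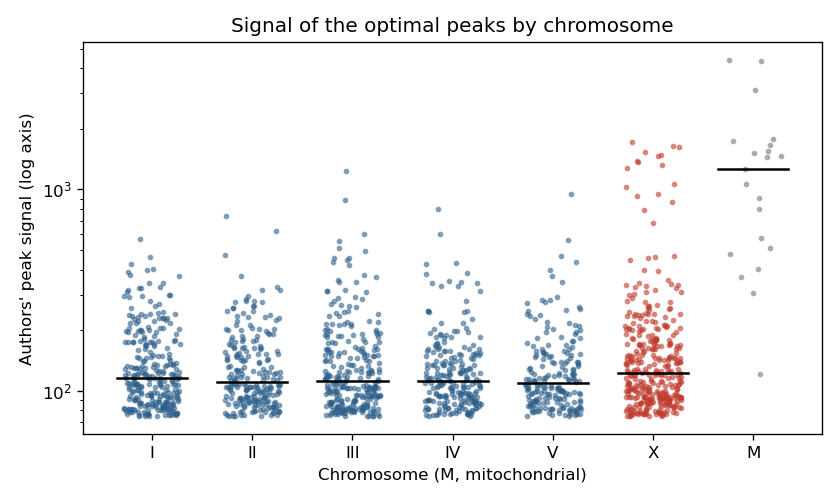
Authors' signal of each optimal peak (points, log axis) by chromosome, with the median as a black line. Medians lie between 110 on V and 123 on X for the nuclear chromosomes, X has a separate upper cloud that reaches 1720, and the mitochondrial chromosome (M) has a median of 1264.

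Short GC-rich sequences and GA repeats were more frequent at the summits than in their flanks. GAGAGA lay within 50 bp of 29.4% of the summits against 7.57% of flanks of equal total length 250 to 300 bp away (adjusted exact p = 1.75e-54), GACGCA within 19.1% against 2.48% (adjusted exact p = 8.86e-51) and ACGCAG within 18.9% against 2.80% (adjusted exact p = 9.54e-48). ACGCGC lay within 13.4% against 1.08% (12.4 times, adjusted exact p = 1.54e-44), a ratio that was 7.83 without replicate 1, 5.97 without replicate 2 and 6.04 within 100 bp of the summit. A/T-rich words were rarer at the summits, with AAAAAT in 20.7% against 49.4% and AAAATT in 14.5% against 41.4%. Of 2080 6-mers, 633 were more frequent at the summits and 485 less frequent (exact McNemar tests, Benjamini-Hochberg adjusted). The mean GC content within 50 bp of nuclear summits was 49.2% ± 8.01 (SD over 1553 peaks) against 36.2% ± 8.32 in the flanks. No background matched for GC content or for promoters was used. The word tests therefore do not separate sites of ROW-1 from the base composition or promoter sequence at the summits. Among 8-mers, AGACGCAG had the smallest p, with 11.5% of summits against 0.890% of flanks, which joins GACGCA and ACGCAG into one word. Among words more frequent at the summits, GACGCA had the smallest p on the autosomes alone (20.97% against 2.58%), and GAGAGA on X alone (30.2% against 6.27%). Both words were called on both: GAGAGA lay within 29.7% against 8.07% on the autosomes, and GACGCA within 13.7% against 2.28% on X.

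**Figure D4:**
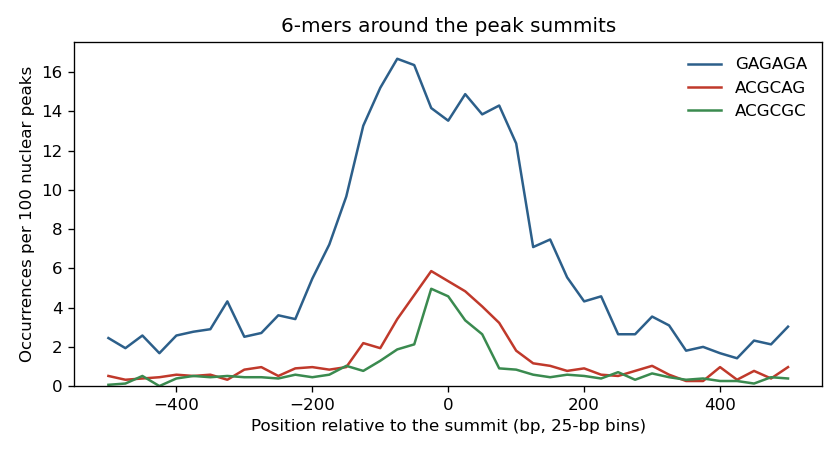
Occurrences of GAGAGA, ACGCAG and ACGCGC per 100 nuclear peaks (y axis) in 25-bp bins around the summit (x axis, bp). ACGCAG and ACGCGC peak at 5.86 and 4.96 in the bin 25 bp before the summit, while GAGAGA is spread more widely around it with a highest value of 16.7.

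The same libraries gave lists of different length on the older assembly ce10. The optimal list had 2157 peaks on ce10 and 1574 on ce11, a ratio of 1.37, with 21.7% and 22.3% of the peaks on X. On each assembly the optimal list was exactly the top of the 30000 pooled calls by signal, down to 60.5 on ce10 and 74.8 on ce11. Of the 2157 ce10 peaks, 2131 (98.8%) had a ce11 pooled call of the same signal (within 0.1%) less than 1 kb away on the same chromosome, against 3.65 on average after circular shifts (one-sided permutation p = 0.001), and 2157 ce11 pooled calls reached the ce10 limit. The replicate lists differed little in number, with 28331 calls on ce10 and 28339 on ce11 for replicate 1, and 25345 and 25405 for replicate 2. The most frequent call width of replicate 2 was 436 bp on ce10 and 430 bp on ce11, while those of replicate 1 (440 bp) and of the pooled list (430 bp) did not change.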

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

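The mitochondrial test below was chosen after its result was seen. The optimal list held 21 peaks on the mitochondrial chromosome, which none of the gene or chromosome tests used. They had a median signal of 1264, 11.1 times the 114 of nuclear peaks, and the highest was 4375. They covered 68.9% of the mitochondrial chromosome, and calls of replicate 1 and replicate 2 covered 60.8% and 66.3%. Cover this broad is consistent with reads from the many copies of the mitochondrial genome rather than with local binding, and the coverage of a control library, which would separate these, was not used here. No biological explanation was tested.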

How the results depend on the processing

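Alternatives restricted to nuclear peaks were chosen after seeing the data. The replicate overlap (53.5% to 79.9%), the promoter share (47.1% to 79.4%) and the X and central shares kept their direction and side of the threshold under each alternative run for them, as did the depletion of coding exons, introns and 3' UTRs. The 787 strongest peaks gave a correlation of 0.784. They also left noncoding exons (0.508%) and intergenic sequence (19.9%) short of the threshold, with fewer peaks tested. The window from 250 bp upstream to 100 bp downstream gave 1.59% for noncoding exons, no longer called, and turned intergenic sequence to an excess (30.8%), as did protein-coding genes only (33.2%); both count as intergenic some sequence that was promoter before. The 5' UTR share was 0.445% by peak overlap, below its shifts, and 0.699% to 0.889% with either replicate alone, called in 1 of them.

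Of 16 called lists, 8 were called in all 9 alternatives. Genes with any pooled call as background, a smaller set, left 7 enriched lists and 1 depleted, and circular shifts left 1 depleted. Against genes with any pooled call, the odds ratio of cytosolic ribosomal protein genes was 8.52 (60.3% against 15.1%) rather than 26. That of spliceosome genes was 3.04 rather than 7.89. Spliceosome and vulval induction genes passed there only narrowly (adjusted exact p = 0.0459 for each). Depleted lists numbered 5 with either other window and 6 with the 3148 strongest pooled calls. With 1 replicate alone there were 11 to 15 enriched and 3 to 4 depleted lists.

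Lists that were not called changed side of their background as follows; the cause was not tested. Circular shifts, whose background is lower, did so for collagens (1.28%), nuclear hormone receptors (1.86%), homeobox (3.66%), muscle (3.33%), cilia (2.63%), germline (2.5%) and Wnt genes (3.45%). Muscle also did so in the narrow window (3.33%), with more pooled calls (13.3%) and without replicate 1 (6.67%; 3.33% without replicate 2). Wnt genes did so in the wide (6.90%) and narrow (3.45%) windows, by nearest gene (10.3%) and in the 787 strongest peaks (3.45%). Aminoacyl-tRNA synthetases did so by nearest gene (6.25%) and against genes with any call (11.8%), histones in the 787 strongest peaks (2%), and spermatogenesis genes there (0%) and with 1 replicate alone (0% to 4.17%). Among the other values of single lists, gene types, sequences and named genes, 368 kept their direction and call (or, untested, moved by less than the SD between replicates), 22 lost and 21 gained a call, and 77 percentile ranks of named peaks moved by more than the SD between replicates. Unknown read depth limits how far weaker peaks can be compared.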

Other observations

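The shares of noncoding genes, the promoter shares of X and autosomal peaks, the GAGAGA comparison, the test of reads from X and the tests on tRNA genes, with the gene families weighed beside them, were chosen after the data were seen. Genes of tRNAs, snoRNAs and snRNAs carried peaks more often than protein-coding genes (4.58%). tRNA genes had a promoter peak in 140 of 612 cases (22.9%, exact 95% interval 19.6 to 26.4, odds ratio 6.19, adjusted exact p = 9.06e-53), and snoRNA genes in 74 of 346 (21.4%, interval 17.2 to 26.1, adjusted exact p = 1.62e-27), by two-sided Fisher's exact tests adjusted over 7 gene types. Counting only peaks outside protein-coding promoters left 118 tRNA genes (19.3%) and 52 snoRNA genes (15.03%). snRNA genes had 14 of 129 (10.9%, adjusted exact p = 0.00358), led by sls-2.1 (chromosome II, 5844865 to 5844974, signal 622), sls-2.4 (569) and sls-2.2 (470), which encode the SL2 RNA spliced onto downstream messages of operons. piRNA genes had 33 of 15363 (0.215%) and pseudogenes 10 of 2128 (0.470%), below protein-coding genes (adjusted exact p = 1.02e-180 and 6.15e-28). These exact tests treat genes as independent, although neighbouring genes can share a peak or lack one together. Against circular shifts, with means of 0.899% and 0.921%, both were lower with weaker p-values (adjusted two-sided permutation p = 0.0028 and 0.028). miRNA genes (18 of 261) and lincRNA genes (5 of 194) did not differ from protein-coding genes past the threshold (adjusted exact p = 0.115 and 0.226). Against circular shifts of the peaks, miRNA genes were above the shifted mean (6.90% against 1.16%, adjusted two-sided permutation p = 0.0028) and lincRNA genes did not pass (adjusted permutation p = 0.114).

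Strong X peaks differed from autosomal ones in place as well as in number. Of the 100 strongest nuclear peaks, 14 of the 36 on X lay at promoters (38.9%) against 50 of the 64 on autosomes (78.1%, two-sided Fisher's exact p = 0.000171). Circular shifts of these peaks gave 22.4% on X and 25.2% on autosomes, and the difference between the shares exceeded that of the shifts (two-sided permutation p = 0.0020). Over all nuclear peaks the shares were 62.4% on X and 70.5% on autosomes (two-sided Fisher's exact p = 0.00489), 2.78 and 2.76 times their shifted means. Against shifts the difference did not pass (two-sided permutation p = 0.0579).

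A hypothesis for the strongest X peaks is that they lie at sites that recruit the dosage compensation complex, which binds X in hermaphrodites and is loaded at a known motif, TCGCGCAGGG. With up to 1 mismatch within 200 bp of the summit, the motif was present at 44.4% of the 36 X peaks among the 100 strongest nuclear peaks and at 1.56% of the 64 autosomal ones (two-sided Fisher's exact p = 7.16e-08), at 13 of the 16 X peaks in the top 20, and at 2.86% of the 315 weaker X peaks. More reads from the whole of X would raise strong and weak calls by the same fold. At 1 pooled call per Mb, the signal reached on X was 1.69 times that on autosomes (bootstrap 95% interval 1.22 to 3.68). At 100 calls per Mb it was 1.06 times (0.989 to 1.13). These intervals do not overlap, so a rise of the same fold in strong and weak calls was not seen. At 20 calls per Mb the X ratio was 1.22 (1.09 to 1.40). Ratios of single autosomes to the others also fell from 1 to 100 calls per Mb on III (1.39 to 1.18) and I (1.17 to 1.12). They did not fall on II, IV or V. The bound set for excluding more reads was not met, as the first interval is wide, so this test cannot exclude them. Higher GC content at strong X summits is argued against, as they did not exceed strong autosomal ones (44.4% ± 8.59 and 47.3% ± 6.42, SD over peaks). The difference was -2.93 percentage points (two-sided permutation p = 0.0561). Other X peaks had 48.4%, above the strong X peaks (permutation p = 0.00178), so a link with lower GC content stays open. It stays open whether ROW-1 binds there itself or whether accessible sites may yield signal with any GFP-tagged protein, since no other tagged strain was used here, and the design gives no group that tests a biological cause.

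For the peaks at ribosomal protein genes, a candidate explanation is signal at strongly transcribed genes whatever the polymerase. The share of tRNA genes with a peak (22.9%), which RNA polymerase III transcribes, goes with it, as do those of respiratory chain (35.3%), translation factor (28.9%) and heat shock genes (26.5%). A peak was found at 2 of 156 collagen genes (1.28%), 1 of 30 muscle genes, 0 of 31 major sperm protein genes and 0 of 29 intestine genes, none of these lists past the threshold. Some of these genes are often transcribed strongly in larvae too, but not every member need be at the L4 stage. As no expression values were used here, this explanation stays open. So does the ACGCAG sequence, which lay within 50 bp of the summit in 8 of 41 peaks at ribosomal protein genes (19.5%, exact 95% interval 8.82 to 34.9) and in 18.8% of 664 peaks at other protein-coding genes (two-sided Fisher's exact p = 0.840), since a comparison within called peaks does not decide. GAGAGA lay in 12.2% of the 41 and 23.5% of the 664 peaks (two-sided Fisher's exact p = 0.124), which leaves it open as well, and other sequences and binding by ROW-1 without one were not tested.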
